A study of Mus musculus with 18 samples.

How the data were processed

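RNA was sequenced from pooled duplicate cultures, per the labels' protocols, so each condition is 1 library. Bowtie is named as a tool and mm9 as the genome build, per the submitters' processing notes; versions, the read counter and the RPKM denominators are not given in the sources used here. The authors deposited RPKM values (reads scaled to transcript length and to the reads of the library) in 2 tables, 1 row per RefSeq transcript, with 22631 rows and 17818 symbols for ES cells and 22630 rows and 17813 symbols for MEFs. Each table also holds a deposited ratio of knockout to wild-type RPKM, which equals the quotient of its 2 columns and is empty where either is 0 (2577 and 3037 rows). It was checked and then not used further. Gene starts and ends are the deposited mm9 coordinates. Reads per library are unknown. RPKM summed over symbols to 318250 in ES3 wild type, 306318 in ES3 knockout, 308887 in MEF wild type and 369572 in MEF knockout. Among genes under 0.5 RPKM, the commonest ratio of the 2 libraries was 1.46 for 36 of 2666 ES3 genes and 0.977 for 198 of 3511 MEF genes. The next was 0.969 for 28 ES3 genes and 1.954 for 85 MEF genes. Relative depth was not derived from these few genes.

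Chromatin was immunoprecipitated from ES3 cells. H3K9me3 regions were deposited as starts and ends with no score, as 1 list for wild type, 1 for knockout and 1 for regions found in wild type only; their caller is not otherwise given in the sources used here. TRIM28 peaks carry names that MACS writes, and the authors deposited a score per peak whose scale and threshold are not stated; the lowest value in the 3 lists is 50.01. Each list is 1 call per condition, so no agreement between replicates can be given. Retained and knockout-only H3K9me3 regions were derived by overlap. Libraries of H3K27ac and of Rex1GFP ES cells, a 129/Ola line with a TRIM28 shRNA or an empty vector, were not analysed here, nor were the input libraries.

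Ratios were computed within each table as log2((knockout + 1)/(wild type + 1)) on the RPKM as deposited, with a pseudocount of 1 RPKM. For each symbol the transcript with the highest mean was kept, and genes at 1 RPKM or more in at least 1 of the 2 libraries were called measured. A gene was called higher or lower at 2-fold or more. A gene without signal in wild type was thus measured only through the knockout, and was then called higher by construction. The same holds in reverse for a gene without signal in the knockout. Random lists were drawn from measured genes, so they share this limit. Rows with no symbol (780 and 778), or with a symbol turned into a calendar date (40 and 39), were kept. They took the reference symbol of their RefSeq transcript or, where there was none, the name of the transcript. RefSeq transcripts matched a reference gene table of assembly GRCm38.p6, used for names alone, in 22110 and 22109 rows; the printed symbol was neither the symbol nor a synonym there in 350 and 346 rows, and 117 transcripts had different symbols in the 2 tables. All other symbols are given as deposited.

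The groups, lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes Trim28, the 12 largest and 8 smallest log2 ratios per comparison, up to 4 members per list with the largest absolute ratio, the 10 largest ratios near wild-type-only H3K9me3 regions, and the 5 TRIM28 peaks with the highest score. Its condition that the genes near regions also be higher in Rex1GFP cells was not applied. Further list members past 2-fold, with Nanog, are named as examples and were chosen after their values were seen. There were 22 lists, 17 fixed by name and 5 by symbol pattern: TRIM28 pathway and H3K9 methylation, pluripotency, two-cell stage and MERVL-linked, primitive endoderm, primitive streak and mesoderm, neural and ectoderm, trophectoderm and placenta, imprinted, germline, interferon response and nucleic-acid sensing, p53 targets and apoptosis, cell cycle, fibroblast and extracellular matrix, endothelial, macrophage and leukocyte, skeletal and cardiac muscle, housekeeping, Zfp, Hox, ribosomal protein, Rhox and histone genes. A list with under 3 measured genes has no median. Each median is given as its percentile among 10000 random lists of the same size drawn within 10 bins of mean expression, and stands out below 2.5 or above 97.5.

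Regions overlapped when they shared 1 bp or more. Shares have Wilson 95% intervals, which cover counting error only, and stand beside 100 seeded placements of the same regions on the same chromosome, leaving out its first 3 Mb. A gene was near a region when its start, strand considered, lay within 20 kb. Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter or a filter at 5 RPKM, centring on the median, all transcript rows, a 3-fold threshold, other overlaps (50% of the peak, or within 1 kb), windows of 10, 50 and 100 kb, the TRIM28 peaks with the higher scores, and genes not named Zfp. Centring within 20 bins of gene span, and leaving out genes also near a retained region, were added after seeing the data.

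The calculations were tested on simulated data for the ES3 comparison with 17818 genes, of which 11672 passed the filter. The spread between libraries was chosen and not estimated, and 8-fold changes were planted in genes at 5 RPKM or more. All 200 planted genes were recovered (100%), which so large a change makes near certain at 2-fold. Another 77 genes passed 2-fold, which follows from the chosen spread and gives no rate of false calls in the real libraries. Of 40 unshifted lists, 3 lay outside the middle 95% of random lists. The overlap code found the same 945 peaks as bedtools. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.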

Results

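TRIM28 (KAP1) is a corepressor that zinc finger proteins bring to DNA, where it recruits the enzymes that place the repressive histone mark H3K9me3. Its loss was studied in mouse cells. The labels describe 18 libraries: 6 of RNA and 12 of chromatin, the latter made of 6 input and 6 immunoprecipitated libraries. Values of 4 RNA libraries and 6 lists of chromatin regions were analysed here. The RNA libraries were wild-type and Trim28-knockout ES3 cells, an embryonic stem (ES) cell line of the C57BL/6 strain kept in serum with LIF, and wild-type and knockout mouse embryonic fibroblasts (MEFs). Knockout ES3 cells were taken 4 days and knockout MEFs 5 days after a Cre recombinase switched on by 4-hydroxytamoxifen. The ES table names its columns only wild type and knockout, and they were read as the ES3 libraries because no other ES pair carries both labels. Each group held 1 library, so no spread, p-value or test of a difference between conditions could be had, and a gene was called by the size of its ratio alone. Depth is unknown, since the RPKM tables give no read counts. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes.

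Trim28 itself (NM_011588; mm9 chromosome 7, 13609501 to 13616384) was lower in both knockout libraries. In ES3 cells it stood at 1051 RPKM in wild type and 37.2 RPKM in the knockout, which is 3.54% of the wild-type value (log2 ratio −4.78). In MEFs it stood at 62.8 RPKM and 5.84 RPKM, or 9.29% of wild type (log2 ratio −3.22).

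In ES3 cells, genes of the primitive endoderm, the early lineage that forms the yolk sac, were higher in the knockout. Col4a2 (NM_009932; chromosome 8, 11312805 to 11449287) and Col4a1 (NM_009931; chromosome 8, 11198423 to 11312826), which encode the chains of basement membrane collagen IV, were the genes with the largest ratios. Col4a2 stood at 2.83 RPKM in wild type and 256.7 RPKM in the knockout (log2 ratio 6.07), and Col4a1 at 5.52 and 409.3 RPKM (5.97). Gata4, a transcription factor of that lineage, was listed at 0.649 and 49.5 RPKM (4.94). At the other end stood Trim28 and Nr0b1, a nuclear receptor of the pluripotency network, with 137.3 RPKM in wild type and 5.47 RPKM in the knockout (−4.42).

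Of 23 measured primitive endoderm genes, 22 were at least 2-fold higher in the ES3 knockout and 1 was lower, with a median log2 ratio of 3.26. Besides the collagens and Gata4, Cubn, an endocytic receptor of the visceral endoderm, had a log2 ratio of 4.58, Sox17 of 3.72 and Gata6 of 3.41. Apoe, a lipid carrier that is abundant in wild-type ES3 cells, was the exception, with 944.7 RPKM in wild type and 301.9 RPKM in the knockout (−1.64). Genes of the trophectoderm, the outer layer that forms the placenta, had a median of 1.39, and 10 of 15 were at least 2-fold higher and none lower. The simple-epithelium keratins led that group: Krt8 (NM_031170; chromosome 15, 101827142 to 101834742) had a log2 ratio of 5.12, Krt18 of 4.44 and Krt19 of 3.20, followed by the transcriptional regulator Cited1 at 2.91. Of 24 primitive streak and mesoderm genes with ES3 values, 11 were measured. Of these, 6 were higher and 1 was lower, with a median of 1.06. Wnt3 (2.65), Hand1 (2.63), T (2.38) and Snai1 (2.08) were the largest, and Bmp4 was the lower gene (−1.12). The 14 neural and ectoderm genes went both ways, with 3 higher and 3 lower and a median of −0.16. Among them Zic2 (2.59) and Nes (2.52) were higher, and Gbx2 (−1.53) was lower.

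Pluripotency genes were lower as a group: none of 28 was at least 2-fold higher, 11 were at least 2-fold lower, 17 lay within 2-fold, and the median was −0.78. After Nr0b1 came Esrrb (−2.00), Sox2 (−1.94) and Nr5a2 (−1.81). Nanog stood at 66.1 RPKM in wild type and 25.03 RPKM in the knockout (−1.37). In the TRIM28 pathway list, which holds Trim28 and its partners in H3K9 methylation and DNA methylation, 2 of 28 genes were higher, 4 were lower and the median was −0.27. Dnmt3l, a cofactor of de novo DNA methylation, had a log2 ratio of −1.61, and Zfp57, a zinc finger protein that guards imprints, of −1.33. The H3K9 methyltransferase gene Suv39h1 was higher (1.27).

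Genes of the two-cell stage embryo that are linked to MERVL retroviral elements were higher in the ES3 knockout. Of 25 with ES3 values 17 were measured, with 13 at least 2-fold higher, none lower and a median of 1.77. Members at 0 in wild type were measured only through the knockout, so their calls as higher were fixed by the filter. Ddit4l, a stress-response gene, stood at 2.54 RPKM in wild type and 16.6 RPKM in the knockout (2.31). Zscan4c, Zscan4d and Zscan4f were listed at 6.66, 6.50 and 8.11 RPKM in the knockout and at under 0.01 RPKM in wild type, and BC080695 was listed at 6.69 RPKM in the knockout and at 0 in wild type. Values of these 4 symbols are uncertain. The Zscan4 copies are nearly identical, and Zscan4c and Zscan4d are given at the same coordinates and so count 1 locus as 2 genes. The symbols Zscan4c, Zscan4d and BC080695 differ from those of the RefSeq transcripts they stand beside, and for the transcript of Zscan4f no reference symbol was found.

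Of 28 p53 targets and apoptosis genes, 13 were at least 2-fold higher and none lower, with a median of 0.89. They included the death receptor gene Tnfrsf10b (2.19), Perp (1.93), Ccng1 (1.83) and Plk2 (1.69), and the cell cycle inhibitor Cdkn1a stood at 29.7 RPKM in wild type and 79.4 RPKM in the knockout (1.39). Interferon response and nucleic-acid sensing genes had a median of 0.69, with 9 of 23 higher and 3 lower. The higher ones were led by Gbp2 (3.02) and by antigen-processing genes, Tap1 (2.85), Psmb8 (2.18) and B2m (1.84), whereas the sensor genes Ddx58 (−1.69), Oas1a (−1.53) and Oas1g (−1.43) were lower. Cell cycle genes mostly lay within 2-fold, 26 of 28, with a median of −0.31. The exceptions were Ccnd2, a D-type cyclin (3.00), and Ccne1, an E-type cyclin (−1.05).

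Markers of other cell types also differed between the ES3 libraries. Of 27 fibroblast and extracellular matrix genes with ES3 values, 18 were measured. Of these, 11 were higher and none lower, with a median of 1.04. Tagln, an actin-binding protein (5.65), Col1a1 (2.94), Vim (2.54) and Acta2 (2.40) were among the higher ones. Endothelial genes had a median of 1.15, with 6 of 11 higher and 1 lower; Cdh5 (2.69), Flt1 (1.94), Tie1 (1.78) and Eng (1.47) had the largest ratios. Only 3 macrophage and leukocyte genes were measured, with a median of −0.80, and Laptm5 was the one past 2-fold (−1.19). Of 7 skeletal and cardiac muscle genes, 1 was higher, Tnnc1 (1.36), with a median of 0.48. None of 18 housekeeping genes passed 2-fold, and their median was −0.16; Eef1a1 (0.60) and Polr2a (−0.58) were among the farthest from 0.

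Imprinted genes, which are expressed from 1 parental copy, went both ways, with 9 of 40 higher, 4 lower and a median of 0.31. Igf2, a fetal growth factor, had a log2 ratio of 3.65, Osbpl5 of 2.60 and Grb10 of 2.34, and Cobl, an actin nucleator, of −3.58. Germline genes that are silenced by promoter methylation had a median of 0.30, with none of 18 higher and 2 lower, Tex19.1 (−1.17) and D1Pas1 (−1.12), and the median was −0.31 (percentile 4.51) with a filter at 5 RPKM. Among 270 genes named Zfp, 249 lay within 2-fold, 17 were higher and 4 lower, with a median of 0.11; Zfp575 stood apart at 4.44, ahead of Zfp992 (1.94), Zfp991 (1.80) and Zfp362 (1.65). Of 47 histone genes, 10 were higher and none lower, with a median of 0.47; Hist1h1c (2.47) led them, and symbols of histone genes differ from those of their RefSeq transcripts, which leaves single members uncertain. Of 73 ribosomal protein genes, 72 lay within 2-fold and Rpl39l was higher (2.37), with a median of −0.07. Only 4 Hox genes were measured (2 higher, median 0.91), led by Hoxc13 (1.34), and 2 Rhox genes, for which no median is given.

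Other genes among the largest ES3 ratios were Srgn, a granule proteoglycan (5.75), the lipoxygenase gene Alox15 (5.43), the secreted peroxidase gene Gpx3 (5.00), Cthrc1 (4.98), the small heat shock protein gene Cryab (4.81), the lectin gene Cd209c (4.68) and 4933409K07Rik (4.62), which lies in a repeated locus and is uncertain. Among the lowest were Gm216 (−3.34), Gpa33 (−3.21), the keratin gene Krt42 (−3.13) and the homeobox gene Nkx6-3 (−2.97). Snord43, a small nucleolar RNA, stood at 6.42 RPKM in wild type and was listed at 0 in the knockout.

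Across 12024 ES3 genes at 1 RPKM or more in either library, 1508 were at least 2-fold higher in the knockout and 382 at least 2-fold lower, so that 79.8% of the calls were higher. Centred on the median the counts were 1295 and 462, or 73.7% higher. Genes of low expression tended to higher ratios, with a rank correlation of ratio and mean expression of −0.262 (0.346 in MEFs). The cause of this tilt was not tested. Each list median was set beside 10000 random lists of the same size and expression, as a description of these 2 libraries. Medians above the middle 95% of random lists belonged to primitive endoderm, two-cell stage, trophectoderm and p53 genes (each at 100), fibroblast (99.99), endothelial (99.95), streak (99.69), interferon (99.39) and histone genes (98.9). Below it lay pluripotency (0), macrophage (1.27) and TRIM28 pathway genes (2.18). In between were ribosomal protein (97.18), imprinted (96.4), Hox (91.51), muscle (83.95), germline (64.48), housekeeping (50.63), neural (5.01), Zfp (4.28) and cell cycle genes (3.92). The size of medians of low genes rests on the pseudocount: that of the two-cell stage list was 4.51 with 0.1 RPKM and 0.57 with 5 RPKM, that of the streak list 2.90 and 0.29, and that of the fibroblast list 2.36 and 0.42. A pseudocount of 5 RPKM brought the streak (95.48), histone (96.49), macrophage (5.65) and TRIM28 pathway lists (3.24) back inside this range, and a filter at 5 RPKM did so for the TRIM28 pathway (2.98) and histone genes, whose median was then −0.05 (17.97). The reverse held for imprinted genes (98.48 with a pseudocount of 0.1 RPKM, 99.46 with the filter at 5 RPKM), ribosomal protein genes (98.04 with that filter) and neural genes (1.57 when ratios were centred within bins of gene span).

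**Figure D1:**
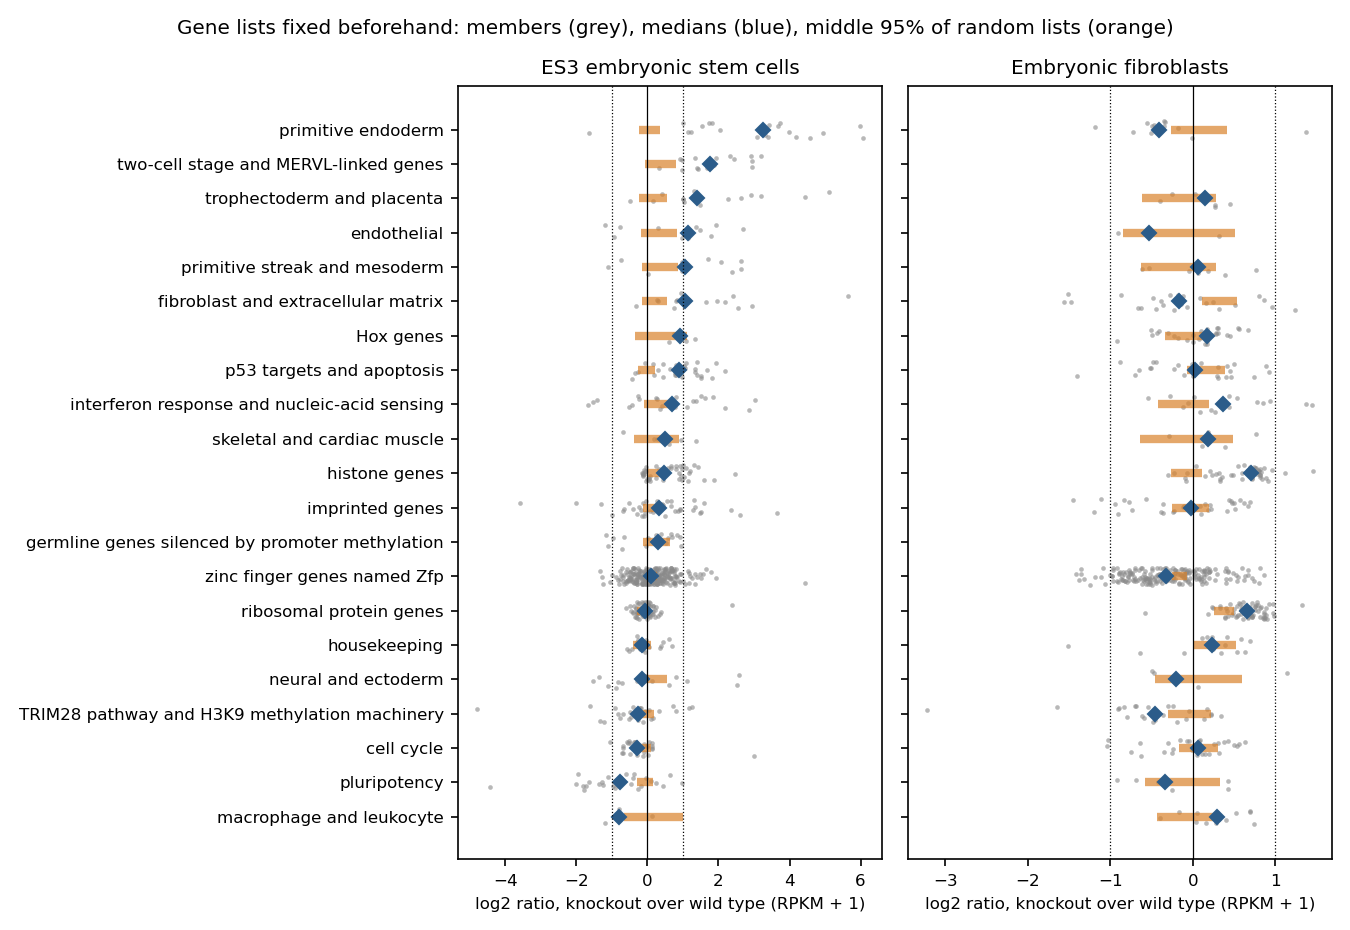
Each grey point is 1 measured gene of a list, placed by its log2 ratio of knockout over wild type on the RPKM + 1 scale (horizontal axis), for ES3 cells on the left and MEFs on the right; blue diamonds are list medians, orange bars the middle 95% of 10000 random lists, and dotted lines 2-fold. In ES3 cells the primitive endoderm median lies at 3.26 and the pluripotency median at −0.78, while in MEFs no list has a median past 2-fold.

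In MEFs, fewer genes passed 2-fold, and more were lower than higher. Inhba, which encodes a subunit of activin, had the lowest ratio after Trim28 among genes above 0 in both libraries, with 321.6 RPKM in wild type and 68.5 RPKM in the knockout (−2.22). The metalloprotease gene Adamts12 (−2.17), Xist, the RNA that silences an X chromosome (−2.02), the BMP receptor gene Bmpr2 (−1.98) and the nucleoporin gene Ranbp2 (−1.90) were also among the lowest. Of the 106 higher genes, 55 were among the 10% with the shortest spans. The largest ratios were those of the Y RNA gene Rny3 (1.96), Gchfr (1.84), Tcfl5 (1.65), Scand1 (1.61), 1700007K13Rik (1.57), Hint2 (1.49), the ribosomal 5S gene Rn5s (1.47), 2610524H06Rik (1.47), Isg15 (1.44) and Wnt4 (1.40). Snord87 stood at 4.48 RPKM in wild type and was listed at 0 in the knockout, and Snord35b was listed at 0 in wild type and at 1.65 RPKM in the knockout. Hist2h4 (1.45) is uncertain, since the ES and MEF values come from different transcripts of that symbol.

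Gene span, the genomic distance from start to end, set the MEF ratios apart from those of ES3 cells. The rank correlation of span and log2 ratio across genes, which are not independent replicates, was −0.543 in MEFs and 0.074 in ES3 cells. In MEFs the median log2 ratio was 0.48 in the 10% of genes with the shortest spans and −0.46 in the 10% with the longest, against 0.03 and 0.23 in ES3 cells. Ratios were therefore also centred within 20 bins of span, an alternative chosen after seeing the data, and its values stand beside each group it changes. Centred in this way, Hint2 (0.96), Rn5s (0.94), Hist2h4 (0.92), Isg15 (0.91) and Snord35b (0.88) were under 2-fold.

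**Figure D2:**
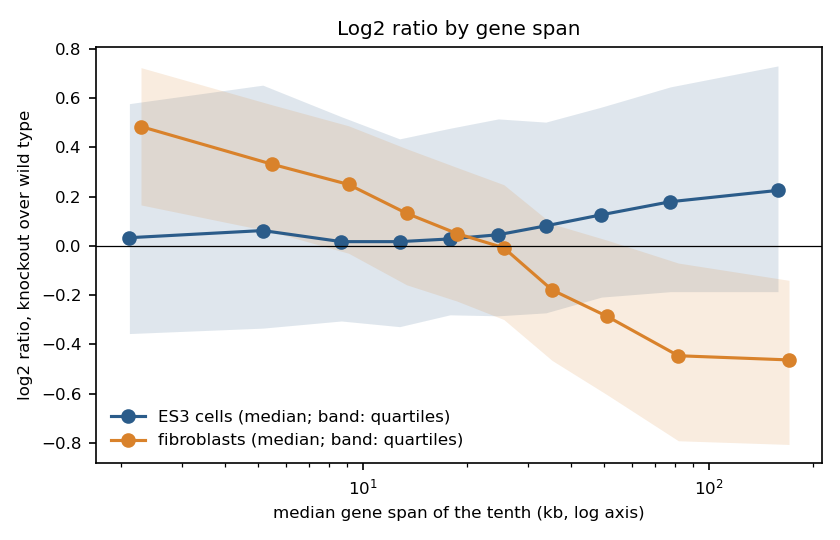
Median log2 ratio of knockout over wild type (vertical axis) in 10 groups of genes ordered by span (horizontal axis, kb, log scale), for ES3 cells in blue and MEFs in orange; bands run from the lower to the upper quartile of genes. The MEF medians go from 0.48 in the shortest group to −0.46 in the longest, and those of ES3 cells from 0.03 to 0.23.

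Matrix genes of the fibroblasts themselves were among the lower ones. Of 26 fibroblast and extracellular matrix genes, 3 were lower and 1 was higher, and the median of −0.17 (−0.11 after span centring) lay below nearly all random lists under both scalings, at percentiles of 0 and 0.03. Postn, or periostin, stood at 420.7 RPKM in wild type and 141.8 RPKM in the knockout (−1.56), Fbn1, or fibrillin, at 78.3 and 26.7 RPKM (−1.52), and Fn1, or fibronectin, at 1711 and 613.3 RPKM (−1.48). The transcription factor gene Twist2 was higher (1.24). Genes named Zfp had a median of −0.32 (percentile 0), with none of 200 higher and 10 lower, and a median of −0.40 after span centring; a filter at 5 RPKM moved it to −0.12 (percentile 33.07). Zfp871 (−1.42), Zfp462 (−1.38), Zfp644 (−1.36) and Zfp445 (−1.35) had the largest ratios, and of these Zfp462 (−0.93) and Zfp644 (−0.89) were under 2-fold after the centring.

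Histone genes had a MEF median of 0.71 (percentile 100), and of 0.19 after span centring (99.92). Of 46, 44 lay within 2-fold and 2 passed it, Hist2h4 and Hist1h4i (1.11). Neither did after the centring, with Hist1h4i at 0.58. Ribosomal protein genes had a median of 0.66 (percentile 100), which span centring took to 0.24 (79.82). Of their 70 members 69 lay above 0 and 1 passed 2-fold, Rpl39l (1.32, and 0.98 after the centring). Interferon response genes had a median of 0.37 (99.93) and of 0.14 (94.37) after span centring, with 2 of 17 higher, Isg15 and Bst2 (1.37, and 0.94 after the centring). Macrophage and leukocyte genes, 13 of them and none past 2-fold, had a median of 0.29 (97.92), which lay inside the range of random lists after span centring (0.04, 69.32) and with a filter at 5 RPKM (94.89). Hox genes had a median of 0.17 (98.88) that turned to −0.25 (2.32) after span centring, and none of 29 passed 2-fold.

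In the TRIM28 pathway list, 2 of 25 MEF genes were lower, Trim28 and the chromatin remodeller gene Atrx (−1.65); the median of −0.46 (0.08) became −0.21 (2.64) after span centring. Primitive endoderm genes, which stood out in ES3 cells, had a MEF median of −0.42 (0.4) and of −0.03 (25.29) after span centring, with 1 of 12 higher, Apoe (1.38, and 0.95 after the centring), and 1 lower, Lamc1 (−1.19, and −0.74). The 6 measured pluripotency genes lay within 2-fold, with a median of −0.34 (15.43) and of −0.56 (0.82) after span centring. Imprinted genes had a median of −0.03 (46.68) and of 0.01 after span centring, with none of 33 higher and 3 lower: Peg3, a paternally expressed zinc finger gene (−1.45), Slc38a4 (−1.19, and −0.87 after the centring) and Ube3a (−1.11, and −0.72).

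The remaining MEF lists lay inside the middle 95% of random lists. Their medians were 0.03 for 27 p53 targets (12.02; Trp53inp1 lower at −1.41), 0.23 for 18 housekeeping genes (33.94; 0.07 after span centring; Tfrc lower at −1.52), 0.15 for 6 trophectoderm genes (89.94; 0.08 after it), −0.21 for 4 neural genes (11.42; −0.14 after it; Tubb3 higher at 1.15, and 0.93 after span centring) and −0.53 for 3 endothelial genes (12.26; −0.28 after it). Medians of 28 cell cycle genes (0.06, 38.99), 7 streak genes (0.06, 82.57) and 5 muscle genes (0.18, 75.43) turned negative after span centring, to −0.11, −0.28 and −0.11. The cell cycle genes Kif11 (−1.05) and Top2a (−1.03) were at least 2-fold lower, and stood at −0.80 and −0.86 after the centring. Only 1 two-cell stage gene and 2 germline genes were measured, and no Rhox gene, so no median is given. Across 10805 MEF genes, 106 were at least 2-fold higher and 523 at least 2-fold lower; after span centring the counts were 87 and 286, of which 23 and 199 were among the first.

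ES3 cells and MEFs were compared to see which genes differed alike. Higher in both knockouts were Wnt4, a secreted signalling protein (2.55 in ES3 cells and 1.40 in MEFs), Dcxr (2.62 and 1.40), Rpl39l (2.37 and 1.32), Crip2 (1.80 and 1.03) and Lgals3 (1.39 and 1.30). Twist2 (1.24 in MEFs) was another, listed at 0 in ES3 wild type and at 1.03 RPKM in the ES3 knockout. Lower in both were Trim28, the Polycomb gene Suz12 (−1.10 and −1.12), the Hedgehog receptor gene Ptch1 (−1.47 and −1.03), Slc38a4 (−1.29 and −1.19), Slc25a36 (−1.29 and −1.36) and Ly75 (−1.44 and −1.24), besides 5 small nucleolar RNAs. These genes, other than Trim28, Wnt4, Rpl39l, Twist2 and Slc38a4, were chosen after their values were seen. The 5 small nucleolar RNAs span only 64 to 90 bp, so a few RPKM can stand for few reads and their calls are uncertain. After span centring only Wnt4, Lgals3, Trim28, Slc25a36 and the 5 small nucleolar RNAs of those named were past 2-fold in both; in MEFs Rpl39l stood at 0.98, Dcxr at 0.87, Crip2 at 0.69, Slc38a4 at −0.87, Suz12 at −0.92, Ptch1 at −0.71 and Ly75 at −0.73, and in ES3 cells Twist2 was under 2-fold. Among 9932 genes measured in both pairs, 1100 were higher in ES3 cells and 90 in MEFs, and 23 were higher in both, where independent lists would share 9.97; after span centring 13 were, against 7.25. With 189 and 460 lower genes, 11 were lower in both, against 8.75 for independent lists (14 against 6.14 after the centring), and 61 genes were higher in ES3 cells and lower in MEFs, against 50.95 (23 against 22.97). The log2 ratios had a Pearson correlation of −0.066 and a Spearman correlation of −0.105 across genes, and of −0.026 and −0.061 after the centring. Whether the 2 tables were normalized together is not given in the sources used here, so this comparison uses ratios within a table.

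H3K9me3 was mapped in ES3 cells to see which marked regions were called in the knockout too. The wild-type list held 37002 regions covering 45.2 Mb and the knockout list 37221 regions covering 38.1 Mb. Of the wild-type regions, 17945 (48.5%, Wilson 95% interval 47.99 to 49.01) overlapped a knockout region by 1 bp or more, against a mean of 3.20% for the same regions placed at random on their chromosomes. The other 19057 made up the deposited wild-type-only list exactly, which the labels call TRIM28-dependent. These were narrower, with a median width of 581 bp, than the retained regions, with 948 bp. The knockout list had 18884 regions that met no wild-type region, with a median width of 511 bp, nearly as many as the wild type had alone. A region called in wild type only therefore need not depend on TRIM28. The lists hold no signal values, and per the labels H3K9me3 was lowered but still present at this time.

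TRIM28 binding was called in ES3 wild type over input (3099 peaks), in wild type over knockout (2382 peaks) and in knockout over input (1898 peaks); what the last list holds, antibody background or TRIM28 left in the knockout, was not tested. Of the wild-type peaks over input, 76 (2.45%, Wilson 95% interval 1.96 to 3.06) overlapped the knockout list, and 1802 (58.15%) were also called over knockout. The 2 peaks at chromosome 2, 98506234 to 98507638 (score 1794) and 98502228 to 98503617 (score 1142), and that at chromosome 9, 35112636 to 35113420 (score 958.5), were 3 of the 5 with the highest scores and all were in the knockout list too. The other 2 were absent from it: chromosome 8, 81112163 to 81112794 (score 1170), in the span of the bile acid transporter family gene Slc10a7, and chromosome 17, 6948999 to 6949993 (score 913.0), in that of Ezr, which encodes the membrane linker ezrin. Over knockout, the next highest were at chromosome 10, 79201684 to 79203502 (score 659.1), in the span of the mitochondrial RNA polymerase gene Polrmt, and at chromosome 12, 110765443 to 110767005 (score 558.1), 12206 bp from the imprinted gene Meg3. Scores are the authors' own values for each peak. The 3 top peaks shared with the knockout list scored 3100, 2734 and 1706 there, and none of them was called over knockout. Whether scores compare between lists is not stated.

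TRIM28 peaks coincided with H3K9me3 more often than random placement gave. Of the 3099 wild-type peaks, 945 (30.49%, 28.9 to 32.14) overlapped a wild-type H3K9me3 region, against 2.76% at random; 321 met a wild-type-only region and 627 a retained one. Knockout peaks did so in 193 of 1898 cases (10.17%, 8.89 to 11.61), against 2.57% at random. These intervals cover counting error only. Counted by region, 316 of 19057 wild-type-only regions (1.66%, against 0.18% at random) met a wild-type TRIM28 peak. Of 17945 retained regions, which are wider, 563 did (3.14%, against 0.29% at random).

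**Figure D3:**
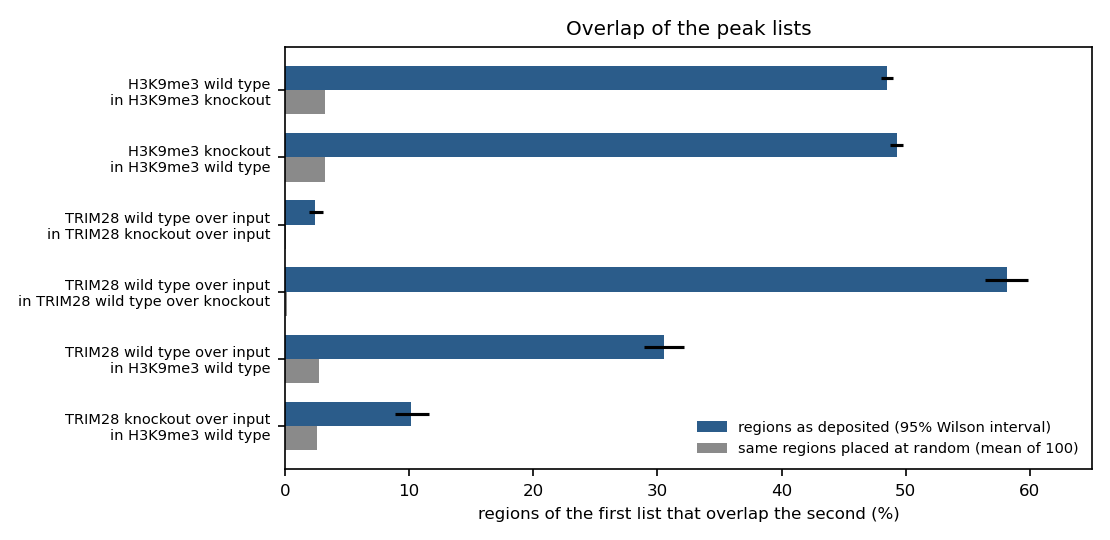
Share of the regions of a first list that overlap a second by 1 bp or more (horizontal axis, percent); blue bars are the deposited regions with Wilson 95% intervals and grey bars the mean of 100 random placements. TRIM28 wild-type peaks meet H3K9me3 in 30.49% of cases and knockout peaks in 10.17%.

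Genes near H3K9me3 regions were then examined in the ES3 libraries to see whether those near wild-type-only regions were higher in the knockout. Among genes starting within 20 kb of a wild-type-only region, the 10 with the largest ratios were Alox15, Krt8, Cthrc1, 4933409K07Rik, the collagen chaperone gene Serpinh1 (4.51), Zfp575, the annexin gene Anxa2 (4.36), Amn, the partner of Cubn (4.17), the stress transcription factor gene Atf3 (4.06) and the myosin light chain gene Myl9 (3.86). The region at chromosome 11, 70162752 to 70163000 lay inside Alox15, that at chromosome 7, 25368920 to 25370508 inside Zfp575, and that at chromosome 9, 69305450 to 69307220 inside Anxa2. Alox15, Cthrc1, 4933409K07Rik and Zfp575 also started within 20 kb of a retained region, and Myl9 within 20 kb of a TRIM28 peak.

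The 1845 genes near wild-type-only regions had a median log2 ratio of 0.14, against 0.10 in random lists of matched expression (percentile 99.24), and 290 of them (15.72%) were at least 2-fold higher, against 13.01%. Without a retained region nearby, a split chosen after seeing the data, the 1387 genes left had a median of 0.09 (48.67) and 14.13% higher against 12.8% (93.79), both inside the random range. The 723 genes near retained regions alone had a median of 0.14 (92.25) and 17.43% higher against 13.03% (99.96), and the 458 near both kinds a median of 0.27 (100) and 20.52% higher against 13.63% (100). Genes near any retained region, 1181 in all, had a median of 0.21 (100), and the 1384 near knockout-only regions of 0.19 (100). Near any retained region 18.63% were at least 2-fold higher, against 13.26% (100). Near knockout-only regions 263 of the 1384 genes were, also against 13.26% (100). With windows of 50 and 100 kb the percentile of the median for wild-type-only regions was 96.38 and 80.0, and that of the share higher was 100 and 99.49.

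Genes near TRIM28 peaks lay inside the range of random lists in ES3 cells. The 863 genes had a median of 0.10 (percentile 91.95), and 108 (12.51%) were at least 2-fold higher, against 12.37% in random lists. For the peaks with the higher scores the median was 0.16 (97.09), and within 100 kb of peaks called over knockout the share higher was 13.43% (97.74), the one value here above that range. Medians were 0.11 (85.71) for 611 genes near peaks called over knockout and 0.08 (61.42) for 629 near the knockout peaks. In MEFs, set beside the ES3 regions for comparison, genes near wild-type-only H3K9me3 had a median of 0.01 (95.6). Of these, 27 (1.74%) were at least 2-fold higher against 0.94% at random (99.96), above the random range. That share was 1.82% against 0.95% (99.66) near retained regions and 0.98% against 0.96% (54.36) near knockout-only ones. MEF genes near TRIM28 peaks had a median of 0.09 (99.91), and those near the knockout peaks of 0.14 (100); span centring was not run for these.

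**Figure D4:**
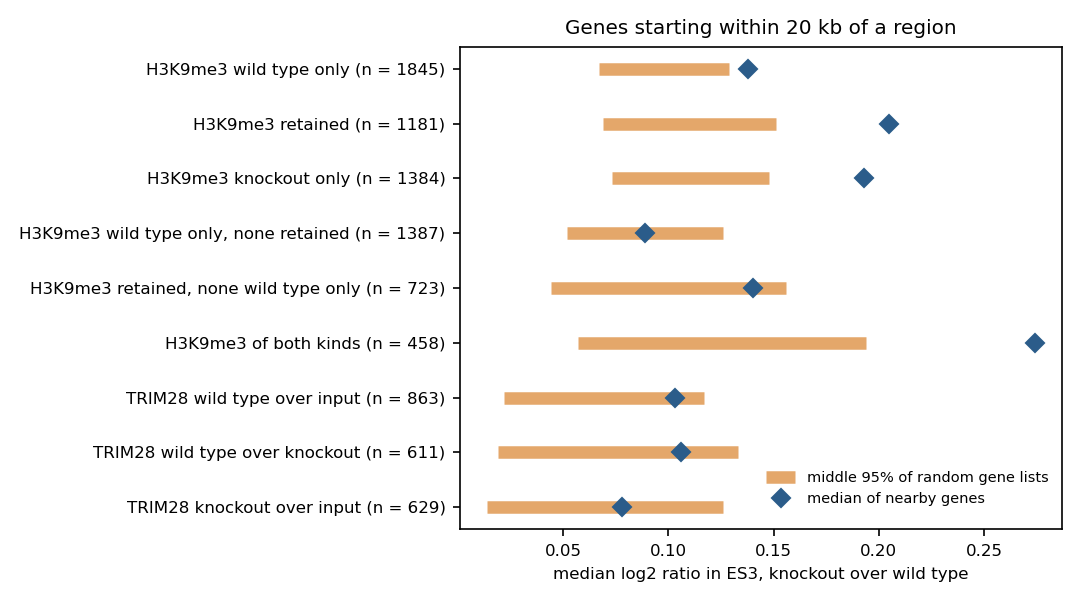
Median log2 ratio in ES3 cells, knockout over wild type (horizontal axis), of genes starting within 20 kb of each kind of region (blue diamonds), beside the middle 95% of 10000 random gene lists of matched expression (orange bars). Genes near both wild-type-only and retained H3K9me3 regions lie at 0.27, above their random lists, and those near wild-type-only regions without a retained one at 0.09, inside them.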

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

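Of the tests below, those of TRIM28 loss as a shared property, fibroblast RNA, Cre induction, lost against retained regions, retained regions alone and wild-type-only regions alone were chosen only after the result was seen. Span centring, on which other tests rest, was also added after seeing the data.

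Several genes and lists went opposite ways in the 2 cell types; these differences were not tested, since each has 1 library per group. Peg3 had a log2 ratio of 1.51 in ES3 cells and −1.45 in MEFs, Bmpr2 of 1.07 and −1.98, Fbn1 of 1.03 and −1.52, and Lamc1 of 1.13 and −1.19. Apoe stood at −1.64 in ES3 cells and 1.38 in MEFs, Rny3 at −1.34 and 1.96, and the small nucleolar RNA Snord87 at 2.01 and −2.45, values that rest on a 0 in ES3 wild type and in MEF knockout. List medians were 3.26 and −0.42 for primitive endoderm, 1.04 and −0.17 for fibroblast and extracellular matrix, and −0.80 and 0.29 for macrophage and leukocyte genes. After centring within bins of gene span, Bmpr2 (0.84), Fbn1 (0.80) and Lamc1 (0.91) were under 2-fold in ES3 cells and Apoe (0.95) and Lamc1 (−0.74) in MEFs, so that of these genes only Peg3, Rny3 and Snord87 kept calls on both sides. In MEFs the medians for primitive endoderm and macrophage genes were −0.03 and 0.04. Rny3 and Snord87 span only 102 and 87 bp, so their values can rest on few reads and their calls are uncertain.

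In MEFs long genes tended to lower and short genes to higher ratios of knockout over wild type. Low expression of long genes does not account for it, because the rank correlation with span was −0.389 or stronger within each of 10 groups of expression. Nor is it a general property of cells without TRIM28, since the correlation was 0.074 in ES3 cells. In MEFs the correlation was −0.442 or stronger on each of 20 chromosomes, which a length-dependent difference between the 2 libraries and an effect of TRIM28 loss on long genes would both give. These cannot be told apart, and spans stand in for transcript lengths, which were not used here.

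Primitive endoderm genes were higher in ES3 knockout cells. In ES3 cells the medians of the 10 groups of span ran from 0.02 to 0.23, so span centring could move the list little. A length trend is argued against by that small size, with a list median of 3.09 after the centring. Fibroblast RNA is too: 25 fibroblast genes gained a median of 0.869% of their MEF level (upper quartile 2.64%), while the endoderm gains would need 156% at their lower quartile, with RPKM set across 2 tables that may differ in normalization. Cre induction and culture cannot be told apart from TRIM28 loss, because only the knockout is labelled as induced and the labels do not say whether wild-type cells were given 4-hydroxytamoxifen; the MEF list, from another cell type given the same induction, had a median of −0.42. A change of cell state after TRIM28 loss remains a hypothesis beside that.

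A larger share of ES3 genes near H3K9me3 regions than of random lists was at least 2-fold higher in the knockout. Near wild-type-only regions alone the share stayed inside the random range. Gene span does not account for the excess where there was one. After span centring the share sat at percentile 100 near wild-type-only, retained and knockout-only regions, and the median at 98.87, 99.99 and 100. Near retained regions alone the share at least 2-fold higher sat at percentile 99.96, though the median was at 92.25. These genes were selected to have no wild-type-only region within 20 kb, so their values cannot test whether loss of a called region matters. An overlap of 1 bp counts as retained, so partial loss of such a region stays open. For genes near wild-type-only regions alone, loss of the called region could be neither shown nor excluded. Their median was at percentile 48.67 and their share at 93.79. The median near lost regions alone minus that near retained ones was −0.05, inside the random range of −0.07 to 0.07. After span centring the share was 17.27% near knockout-only regions, against 11.24% at random, and 13.77% near wild-type-only ones, against 11.09%. The excess was thus not confined to genes near regions called in wild type only, and loss of the mark at a knockout-only region cannot explain it there. Genes near knockout-only regions were not split by other regions nearby, so loss at those was not excluded. A decrease of H3K9me3 at retained regions may matter and stays open, because the lists hold no signal.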

How the results depend on the processing

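Centring within bins of gene span, and leaving out genes also near a retained region, were tests chosen only after the result was seen. Except where stated, the cause of a difference was not tested. With a pseudocount of 0.1 RPKM there were 601 lower genes in ES3 cells and 218 higher and 1053 lower in MEFs; with 5 RPKM, which shrinks low genes by construction, 538 and 164 in ES3 cells and 35 and 87 in MEFs. A filter at 5 RPKM, which tests fewer genes, left 967 higher in ES3 cells, and a 3-fold threshold 595 and 111 in ES3 cells and 4 and 41 in MEFs. Span centring left 286 lower genes in MEFs and turned the Hox median there to −0.25. Genes higher in both cell types numbered 50 and 6 with these pseudocounts, 13 with the filter, 13 after span centring and 0 at 3-fold. The share of H3K9me3 regions in the knockout list was 37.58% when 50% of the region had to be covered and 53.32% within 1 kb; that of TRIM28 peaks in H3K9me3 was 27.11% and 33.75%, and 41.55% for the peaks with the higher scores, 3.94% of which were in the knockout list. Genes near wild-type-only regions had medians of 0.11 within 50 kb and 0.09 within 100 kb, with percentiles of 96.38 and 80.0, and of 0.089 without genes also near a retained region. The other 22 alternatives for counts and shares stayed within 1.5 times or within the interval. Of the list alternatives 175 kept their side of the random range, 14 lost it, 5 gained it and 1 reversed; of those for named genes 693 kept their side of 2-fold, 50 lost it and 21 gained it. Alternatives for Rex1GFP cells, and those for H3K9me3 that need a score, were not run. Depth is unknown, so ratios of genes near 1 RPKM and of very short transcripts are the least certain.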

Other observations

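Setting the 22 gene lists against the chromatin regions was chosen only after the result was seen, as 220 comparisons of lists, 5 region lists and 2 placements, so some high counts arise by chance, and clustered genes share regions.

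Imprinted genes held TRIM28 peaks more often than matched lists. Of 49 imprinted genes in the ES table, 14 had a wild-type TRIM28 peak within their span, against a mean of 3.82 and a highest count of 12 in random lists of like span, 13 had one called over knockout and 5 a knockout peak. Within 20 kb of 20 imprinted genes lay 21 distinct peaks, of which 15 were also called over knockout, 10 overlapped wild-type H3K9me3 and 7 knockout H3K9me3. Nnat, a neuronal membrane protein gene, held the peak with the highest score among them (chromosome 2, 157384869 to 157386701, score 851.8) and stood at 10.4 RPKM in wild type and 33.1 RPKM in the knockout. Nnat was also among the 5 genes with a knockout peak within their span, although its wild-type peak was called over knockout too. Peg3 held a peak at chromosome 7, 6681834 to 6682565, where H3K9me3 was called in wild type only, and stood at 5.18 and 16.6 RPKM. Inpp5f (1.32) and Gnas (1.33) held peaks and were higher, whereas Snrpn (−0.24) held one and lay within 2-fold. Of 17 measured imprinted genes with a peak within 20 kb, 5 were higher and 1 lower, with a median of 0.45; of 23 without, 4 were higher and 3 lower, with a median of 0.20. This difference was not tested.

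Two-cell stage genes lay in H3K9me3 more often than random lists: 14 of 25 had a retained region within their span, against a mean of 1.44 and a highest count of 7 in random lists, and 5 had a wild-type-only region (mean 1.16, highest 6). Zscan4c and Zscan4d share coordinates, so 1 locus counts as 2 of these genes. None held a TRIM28 peak over input, and 5 started within 20 kb of a peak called over knockout (mean 1.29, highest 7), among them the uncertain Zscan4 copies. Genes named Zfp started within 20 kb of a wild-type-only region in 93 of 320 cases (mean 54.57, highest 81), of a retained region in 65 (mean 38.59, highest 61) and of a TRIM28 peak in 35, called over knockout (mean 16.37, highest 34) or over input (mean 22.76, highest 40). Within their span, 15 held a peak over input (mean 13.58, highest 28). No Hox gene of 37 (mean 2.94), histone gene of 55 (4.58), streak gene of 24 (1.8) or Rhox gene of 19 (1.47) started within 20 kb of a TRIM28 peak over input.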
